A study of Vernicia fordii and Jatropha curcas with 4 samples.

How the data were processed

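Gene expression was measured by RNA sequencing of 4 libraries from developing seeds, 2 of Jatropha curcas and 2 of Vernicia fordii. Per the labels' protocols, RNA was extracted with CTAB, polyadenylated RNA was selected, fragmented and made into directional libraries, and inserts were size selected after amplification. Per the series' design text, RNA of 3 seeds was mixed before each library was made, so each library is 1 sample and holds no measure of the spread between seeds.

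The authors deposited 1 table per species with RPKM values (reads scaled to the length of the contig and to the mapped reads of the library) for assembled contigs, rounded to 2 decimals, and with an Arabidopsis locus code of the TAIR10 release, where one was assigned. The unit is taken from the deposited tables' names. Bowtie and edgeR are named in the submitters' processing notes, without versions or roles. The assembler, the search behind the locus codes, the counting and any filter are not given in the sources used here. No contig was at 0 in both libraries of its table. RPKM depends on the total of each library, so a few very abundant contigs can lower all others.

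The labels tie each table to a species, but no label says which of the value columns, numbered 7 and 8, belongs to which stage. Libraries are named by these numbers and no result rests on an assignment to a stage. A table of columns and samples kept with the analysis lists them in ascending order only as a placeholder.

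The files pair contigs with locus codes and with no gene names. The gene lists that had been fixed by name before the data were examined (lipid synthesis, seed storage and other groups) were therefore not used, as the design fixed at that time had laid down, and gene functions are not described. Locus codes for these lists were at one point written from general knowledge, and the values, including those of the most abundant and most changed contigs, were looked at once by list. That table was discarded, no reported value uses it, and all other values were computed afterwards. By the rule fixed then for this case, only the 2 contigs with the largest excess and the 2 with the largest deficit in library 8 are named per species, among contigs with at least 10 RPKM in either library.

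Differences were computed as log2((library 8 + 1)/(library 7 + 1)) in RPKM for contigs with at least 1 RPKM in either library, and contigs at least 2-fold apart were counted. This scale understates the change of low contigs. With 1 library per group no test was run. Relative depth was read from the most frequent ratio among contigs between 0.4 and 1.5 RPKM in both libraries, where values are multiples of 1 read. That ratio was taken to mark equal numbers of reads in both libraries, which was not checked in the data. Intervals of shares are 95% Wilson intervals. They treat loci as independent draws and cover neither read counting error nor variation between seeds. The alternatives were pseudocounts of 0.1 and 5 RPKM, no filter and a filter of 10 RPKM, 4 other scalings and a 4-fold threshold. Median-ratio and trimmed mean scaling divide library 8 by its typical ratio to library 7, among contigs with at least 1 RPKM in both. They therefore remove a shift shared by most contigs, whatever its source. The steps were tested on simulated data in which 200 contigs differed 4-fold: 200 of 200 were recovered in the simulation of the Jatropha comparison, run on 45411 contigs, and 200 of 200 in that of Vernicia, run on 49582. Of the unchanged contigs, 11 of 30984 and 9 of 30839 passed the 2-fold limit. The simulation held read counting error alone, without variation between seeds. Its 200 changed contigs were drawn from those with a mean of at least 10 RPKM, and its contig lengths and read totals were not those of the data. It therefore does not show the recovery of low contigs, or either rate at the real read totals. The ratio of depth, set at 0.9, was read back as 0.9 in both simulations, where most contigs did not differ. How well it is read where many contigs differ was not simulated. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.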

Results

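The series asked how lipid synthesis differs between the developing seeds of 2 oil trees of the spurge family, Jatropha curcas (physic nut) and Vernicia fordii (tung tree). Polyadenylated RNA was sequenced from 4 libraries, 2 per species, each made from the pooled RNA of 3 seeds. One library of each species came from an early stage of oil accumulation and the other from a fast stage, at 29 and 37 days after pollination in Jatropha and at 90 and 135 days in Vernicia. The deposited columns carry the numbers 7 and 8, and no label used here says which number belongs to which stage. The libraries are therefore called library 7 and library 8, and no difference between them is given a direction in time. There were no replicates, so no difference below has a replicate check or a p-value, and differences are described by size alone.

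The deposited tables listed 45411 assembled contigs for Jatropha and 49582 for Vernicia. Their RPKM values summed to 1104588 in Jatropha library 7, 817400 in Jatropha library 8, 676071 in Vernicia library 7 and 751745 in Vernicia library 8. Read totals are unknown. Low RPKM values were read as multiples of 1 read. Their most frequent ratio, library 7 over 8, was 1.11 in Jatropha, where 550 of 5978 low contigs lay at this peak. In Vernicia it was 0.928, with 776 of 9352 at the peak. If these contigs held equal numbers of reads in both libraries, library 8 was the deeper one in Jatropha and library 7 in Vernicia. Other pairs of read numbers could give such a peak, so the order of depth is not certain. An Arabidopsis locus code accompanied 22599 Jatropha contigs (49.8%) and 21611 Vernicia contigs (43.6%). Contigs with a locus code held 58.1% of the RPKM in Jatropha library 7 and 80.7% in library 8, against 79.2% and 76.9% in Vernicia libraries 7 and 8.

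A small number of transcripts held much of the signal in the Jatropha seeds. The most abundant contig alone held 25.1% of the RPKM of Jatropha library 7, at 277426 RPKM, and the most abundant contig of library 8 held 12.1%, at 99181 RPKM. In Vernicia the corresponding shares were 2.61% and 3.76%. The top 10 contigs held 36.2% of the RPKM in Jatropha library 7 and 43.1% in library 8, and 12.4% and 23.3% in Vernicia libraries 7 and 8. The top 100 contigs held 49.3% and 62.9% in Jatropha and 28.4% and 42.6% in Vernicia. In both species library 8 was thus the more concentrated by its top 10 and top 100 contigs.

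**Figure D1:**
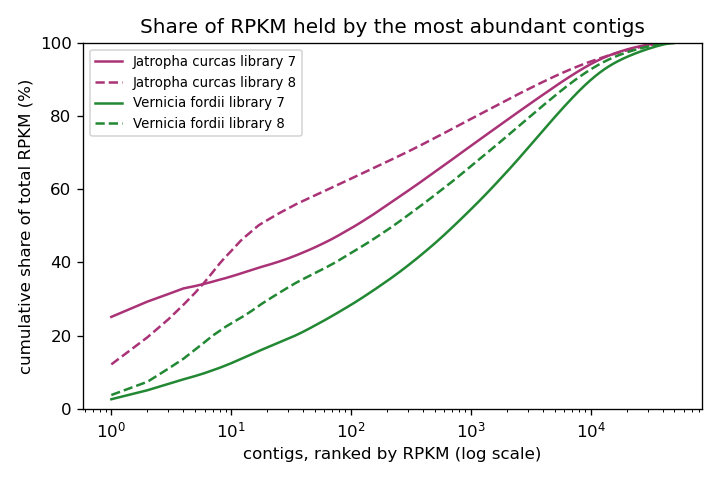
Cumulative share of total RPKM (vertical axis, percent) against contigs ranked by RPKM (horizontal axis, log scale), with 1 line per library and dashed lines for library 8. The Jatropha lines start at 25.1% and 12.1% for the first contig, and the Vernicia lines at 2.61% and 3.76%.

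Fewer contigs reached 1 and 10 RPKM in library 8 of each species as deposited, but not under every scaling. Contigs at 1 RPKM or more numbered 28995 in Jatropha library 7 and 25974 in library 8, and 31062 and 26990 in Vernicia. At 10 RPKM or more there were 9069 and 5277 contigs in Jatropha and 9031 and 7731 in Vernicia. After trimmed mean scaling, an alternative added after seeing the data, library 8 had 33888 contigs at 1 RPKM or more and 8113 at 10 RPKM or more in Jatropha, and 30963 and 9204 in Vernicia. Contigs listed at 0 numbered 4380 in Jatropha library 7 and 1884 in library 8, and 948 and 2000 in Vernicia. At 1000 RPKM or more there were 89 and 52 contigs in Jatropha, and 52 and 53 in Vernicia.

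The comparison of the 2 Jatropha libraries addressed how the seed transcriptome differed between the stages of oil accumulation. Of 36666 contigs with at least 1 RPKM in either library, 6235 were at least 2-fold higher in library 8 and 13583 at least 2-fold lower, on the log2(RPKM + 1) scale. The lower contigs made up 68.5% of the changed ones, but 46.2% after trimmed mean scaling, so the balance of the directions depended on the scaling. The median contig with at least 1 RPKM in both libraries was shifted by -0.83 on the log2 scale. On this scale contig comp27626_c0, which had no locus code, had the largest excess in library 8. It had 6.65 RPKM in library 7 and 3222.55 in library 8, a log2 difference of 8.72. Contig comp13072_c0, matched to AT5G44120 in the deposited table, followed with 19.67 RPKM in library 7 and 6993.89 in library 8, a log2 difference of 8.40. Their order turned with a pseudocount of 5 RPKM, at 8.11 for comp27626_c0 and 8.15 for comp13072_c0. The largest deficit in library 8 was that of comp13116_c0, matched to AT3G24060, with 4852.23 RPKM in library 7 and 2.64 in library 8, a log2 difference of -10.38. Contig comp27723_c0, without a locus code, had 1261.28 and 0.77 RPKM, a log2 difference of -9.48.

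The same comparison in Vernicia gave fewer differences of this size. Of 35689 contigs, 3487 were at least 2-fold higher in library 8 and 5992 at least 2-fold lower. The lower contigs made up 63.2% of the changed ones, but 41.6% after trimmed mean scaling, and the median shift was -0.40 on the log2 scale. At a 4-fold threshold 924 contigs were higher and 587 lower in library 8, so the balance also turned with the threshold. Contigs comp12120_c0 and comp15400_c0, both matched to AT1G03880, had the largest excess in library 8. The first had 14.77 RPKM in library 7 and 27190.22 in library 8, a log2 difference of 10.75, and the second 15.69 and 28250.88 RPKM, a log2 difference of 10.73. Values of contigs that share a locus are uncertain where the counting split reads between near-identical copies. The largest deficits in library 8 were those of comp27100_c0, with 513.38 and 2.08 RPKM and a log2 difference of -7.38, and comp13589_c1, with 134.09 and 1.03 RPKM and a log2 difference of -6.06, neither of which had a locus code.

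**Figure D2:**
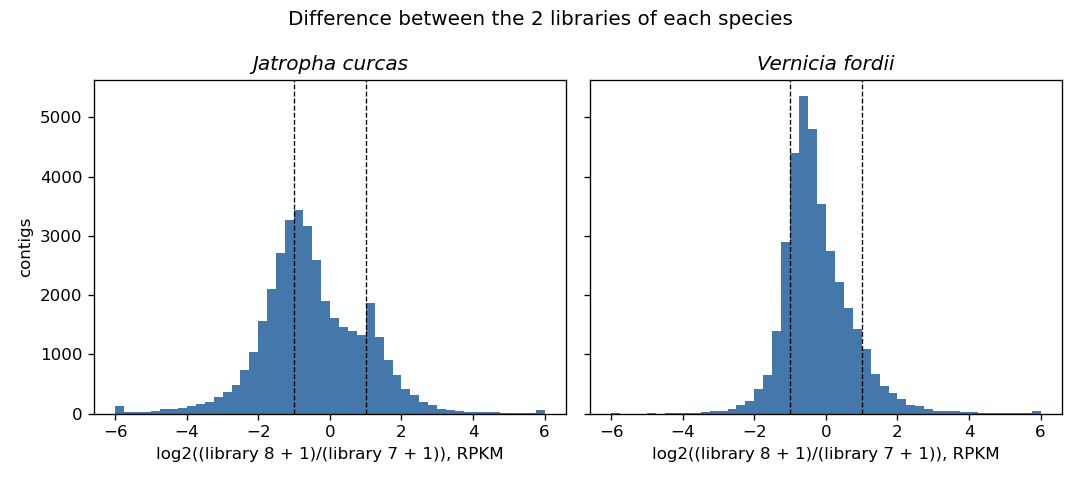
Number of contigs (vertical axis) by log2 ratio of library 8 over library 7 after adding 1 RPKM (horizontal axis; values beyond 6 in size are drawn in the outermost bins), for contigs with at least 1 RPKM in either library. Dashed lines mark 2-fold differences, beyond which lie 6235 higher and 13583 lower contigs in Jatropha and 3487 and 5992 in Vernicia.

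The species were compared through the Arabidopsis locus codes, summing RPKM over the contigs of a locus. The tables were normalized separately, so only the differences within each species were set side by side. The tables shared 11415 loci, of which 11054 had at least 1 RPKM in either library of both species. Across these loci, which are not independent replicates, the log2 differences of the species had a Pearson r of 0.17 and a Spearman rho of 0.07. The difference had the same sign in both species at 7763 loci (70.2%), against 66.4% for independent signs with the same shares of higher and lower loci. The 95% Wilson interval of 69.4 to 71.1% treats loci as independent draws and leaves out read counting error and variation between seeds. After trimmed mean scaling the share was 53.0%, against 51.5%. At least 2-fold higher in library 8 of both species were 205 loci, against 50.2 for independent lists of the same sizes, and 335 against 158.9 after trimmed mean scaling. At least 2-fold lower in both were 1056 loci, against 951.6, and 386 against 216.5 after that scaling, so the ratio moved from 1.11 to 1.78. Loci at least 2-fold lower in Jatropha and higher in Vernicia numbered 312, against 357.2 for independent lists, but 315 against 256.4 after trimmed mean scaling. Those higher in Jatropha and lower in Vernicia numbered 109, against 133.7, and 136 against 134.2 after that scaling. With a pseudocount of 5 RPKM these opposite differences numbered 155 against 158.3 and 40 against 37.4, so whether they fell below or above the number for independent lists depended on the processing. Whether the same library number stands for the same stage in both species is not given in the sources used here.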

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

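The tests of explanations in this part, and trimmed mean scaling for the counts of contigs by level, were chosen after the results were seen, while the pseudocounts, the 4-fold threshold and the scalings used for the differences had been planned before. The species differed in direction at 312 loci that were at least 2-fold lower in Jatropha library 8 and higher in Vernicia library 8, against 357.2 for independent lists, and at 109 loci with the opposite pattern, against 133.7. After trimmed mean scaling these were 315 against 256.4 and 136 against 134.2, and with a pseudocount of 5 RPKM 155 against 158.3 and 40 against 37.4, so no departure from independent lists held throughout. These differences were not tested, as each rests on 1 library per stage, and they presume that a library number means the same stage in both species, which no label states.

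As deposited, contigs lower in library 8 outnumbered those higher in both species, at 68.5% of the changed contigs in Jatropha and 63.2% in Vernicia. The balance turned after median-ratio scaling (46.4% and 41.5%) and trimmed mean scaling (46.2% and 41.6%), and in Vernicia also at 4-fold (38.8%), so the pattern depends on the processing. Both scalings remove a shift shared by most contigs, whatever its source. A turn under them therefore does not tell where that shift came from. A candidate explanation for the pattern is that abundant contigs take more of the reads in library 8. In Jatropha the summed RPKM of the top 100 contigs was slightly lower in library 8, by a log2 value of -0.083, while the total over all contigs differed by -0.43. The explanation was taken to need a higher sum, which presumes that sums of RPKM stand for reads. The value lay within a margin around no difference that was set after the results were seen, so the explanation was left open. In Vernicia the top 100 differed by 0.74 and the total by 0.15, in the direction taken to be needed. These sums follow from the shares and totals already seen, so they are no separate support for the explanation. With equal totals outside the top 100 contigs of either library, the lower share was 51.8% in Vernicia, so the balance did not turn there, and 44.0% in Jatropha. The sum of those other contigs differed by -0.21 in Vernicia, against a median shift of -0.40. Contig lengths are not used here, so the reads behind these sums are unknown, and a difference in most transcripts of the seed stays open in both species.

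As deposited, library 8 of each species had fewer contigs at 1 and at 10 RPKM or more than library 7. After trimmed mean scaling this held in Jatropha at 10 RPKM (8113 in library 8 against 9069) but not at 1 RPKM. In Vernicia it did not hold at 10 RPKM, and the counts at 1 RPKM were nearly equal (30963 in library 8 against 31062). In Jatropha the most frequent low ratio, library 7 over 8, was 1.11. If it marks equal numbers of reads, library 8 was the deeper one, which argues against its lower read depth as the source. Only 550 of 5978 low contigs lay at that peak, and other pairs of read numbers could give it. In Vernicia this ratio was 0.928. By the same reading library 8 was the shallower one, by less than the count at 1 RPKM or more differed (0.869 times as many contigs in library 8). As RPKM is already divided by depth, this ratio decides nothing there, and depth stays open in Vernicia. No biological explanation was tested for these patterns, because the stage of each library is not given.

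Loci at least 2-fold higher in library 8 of both species were 4.08 times the number for independent lists. This was 6.0 times with a pseudocount of 5 RPKM and 2.11 times after trimmed mean scaling. The number for independent lists takes no account of expression level. Opposite differences fell below it as deposited, but reached 315 against 256.4 and 136 against 134.2 after trimmed mean scaling. Whether a library number means the same stage in both species is not known.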

How the results depend on the processing

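The counts of changed contigs depended on the pseudocount, the filter, the threshold and the scaling, and the cause was not tested except where stated. In Jatropha, where 6235 contigs were higher and 13583 lower in library 8 (68.5% lower), the numbers were 1207 and 5523 (82.1% lower) with a pseudocount of 5 RPKM, 977 and 5631 (85.2%) at 10 RPKM or more, where fewer contigs enter, and 1504 and 3905 (72.2%) at 4-fold. Scaling turned the balance: median-ratio scaling gave 9669 and 8373 (46.4%), trimmed mean scaling 9720 and 8337 (46.2%) and equal totals without the top 100 contigs 10109 and 7930 (44.0%), while rescaling to equal totals over all contigs left it at 57.1%. In Vernicia, where 3487 were higher and 5992 lower (63.2% lower), the numbers were 5492 and 11041 (66.8%) with a pseudocount of 0.1 RPKM, 1243 and 1427 (53.4%) with 5 RPKM, 1251 and 2051 (62.1%) at 10 RPKM or more, and 924 and 587 (38.8%) at 4-fold. Median-ratio scaling gave 5232 and 3719 (41.5%), trimmed mean scaling 5228 and 3730 (41.6%), equal totals over all contigs 9239 lower (71.8%), and equal totals without the top 100 a lower share of 51.8%. Removing the filter on low values could not change the counts, since contigs under 1 RPKM in both libraries cannot differ 2-fold with a pseudocount of 1 RPKM, and the direction of the 8 named contigs could not turn under shifts of these sizes. The sizes of the named deficits did move with a pseudocount of 5 RPKM. They were then -9.31 for comp13116_c0, -7.78 for comp27723_c0, -6.19 for comp27100_c0 and -4.53 for comp13589_c1. With a pseudocount of 0.1 RPKM the deficit of comp27723_c0, which had only 0.77 RPKM in library 8, was -10.50, against -9.48. With either pseudocount the named excesses moved less. With the top 10 contigs of each library left out, the next 10 held 4.83% and 14.8% of the remaining RPKM in Jatropha libraries 7 and 8 and 4.91% and 8.31% in Vernicia. Loci at least 2-fold higher in library 8 of both species numbered 127 with a pseudocount of 5 RPKM and 335 with trimmed mean scaling, against 205. Those lower in both numbered 374 and 386, against 1056, while the ratio to independent lists was 1.34 and 1.78, against 1.11. The share of loci with the same sign was 53.0% with trimmed mean scaling. The alternatives planned for the gene lists were not run, because the lists were not used. No paired analysis was possible because each group holds 1 library and no result comes from a test. Read totals are unknown, so the counting error of single contigs could not be given.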

Other observations

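The contigs at least 2-fold higher in library 8 of Jatropha differed in makeup from those lower. Of the 6235 higher contigs, 2773 (44.5%) were listed at 0 in library 7, where 4380 contigs in all were at 0, and 1684 (27.0%) had a locus code. Of the 13583 lower contigs, 1526 (11.2%) were listed at 0 in library 8, where 1884 in all were at 0, and 8691 (64.0%) had a locus code. After trimmed mean scaling the shares at 0 were 28.5% of 9720 higher and 18.3% of 8337 lower contigs, and the shares with a locus code 35.6% and 60.6%. In Vernicia 531 of the 3487 higher contigs (15.2%) were listed at 0 in library 7, where 948 in all were at 0, and 653 of the 5992 lower contigs (10.9%) in library 8, where 2000 in all were at 0. After trimmed mean scaling these shares were 10.2% and 17.5%, so their order turned. In both species the numbers of contigs at 0 were unchanged by that scaling, so the shares at 0 moved only because the lists grew or shrank. A locus code accompanied 44.8% of the higher and 62.1% of the lower Vernicia contigs, and 43.3% and 56.7% after that scaling. These values were looked at after the distribution of the differences had been seen, and no explanation for them was tested.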
